A study of Rattus norvegicus with 12 samples.

How the data were processed

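Total RNA from 12 cultures of neonatal rat cardiac myocytes was hybridised to Affymetrix whole-transcript arrays. Per the labels, the cultures held over 90% myocytes, were grown with bromodeoxyuridine against fibroblasts, were transfected with a non-silencing (NS) or a p300 siRNA, spent 48 h without serum and then received 1 µM doxorubicin (Dox) for 0 or 8 h. The group and the replicate number of each array were read from its title and treatment label, which gave 4 groups of 3. The series design text states 3 experiments, each with NS and p300 siRNA cells at both times.

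The deposited values are intensity values on a linear scale (8.05 to 25315), 1 per probe set, and per the submitters' processing notes they come from Affymetrix Expression Console 1.1 with RMA, which corrects background, normalises between arrays and summarises probes. The notes used here do not state how the values came to be linear; the scale was read from the values, and log2 was taken here. The medians of log2 intensity over all probe sets lay between 7.73 and 7.80 on the 12 arrays, and the SD of log2 differences between 2 arrays of a group between 0.154 and 0.265. The number of arrays limits the precision.

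The table holds 29214 probe sets. The platform annotation gave 1 gene symbol for 15310, several for 323 and none for 13581, and probe sets without exactly 1 symbol were left out. Where a gene had more than 1 probe set (526 genes) the brightest over all arrays was used, which left 14507 genes. Of these, 14481 had their Entrez identifier in a current rat reference table (assembly GRCr8), which was used for names only. No filter on level was applied.

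The 6 comparisons came from 1 model of 4 group means: Dox in NS cells, Dox in p300 siRNA cells, the p300 siRNA at 0 h, at 8 h and averaged over both, and the difference between the drug responses (the interaction). The model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, 8 residual degrees of freedom per gene, two-sided), and p was adjusted by Benjamini-Hochberg over all genes tested within a comparison. A gene passed, or was called, at an adjusted p under 0.05. Log2 changes are the treated minus the untreated and the p300 siRNA minus the NS mean, with SE from the moderated variance. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

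Whether the replicate numbers name the 3 experiments was checked on the deviations of each array from its group mean. The 18 pairs of arrays with 1 number in different groups had a median correlation across genes of 0.504 (0.172 to 0.689), other pairs a median of -0.271, and 12 of 12 arrays were closest to their own number. The replicate number is therefore called the experiment in the text. The model fixed before the data were examined ignores it. The fit with the experiment as a block was among the alternatives fixed with it. Its values are given beside the totals and the list calls that it changes, and beside the larger of the list counts that it moves, not beside each of them.

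Fixed together with that model were 25 gene lists, 19 of pathways and 6 of cell type markers. The pathway lists were p53 targets, immediate early genes, sarcomere, hypertrophy, cardiac transcription factors, calcium handling and ion channels, fatty acid oxidation, oxidative phosphorylation, antioxidant and NRF2 targets, BCL2 family and apoptosis, cell cycle, DNA repair, cytokine and NF-kB, interferon response, heat shock and unfolded protein, HIF targets, acetyltransferases and deacetylases, replication-dependent histones, and TGF-beta and SMAD targets. The marker lists were of cardiac myocytes, fibroblasts, endothelium, smooth muscle and pericytes, macrophages and leukocytes, and erythroid cells. For each list and comparison the members past the threshold were counted, over all genes and adjusted over the list alone, and camera was run with its preset correlation between genes of 0.01, with Benjamini-Hochberg over the 25 lists of a comparison; this is the set test of the text. Of its 49 calls, 0 hold when camera estimates the correlation from the arrays. How often that version misses a list that truly moved was not tested. A call lost with it is therefore not shown to be weaker than another. fry was run beside it and asks whether a list moves on balance, not whether it moves more than other genes. The medians and the set test had 1 sign for every list that was called.

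Genes named in the text followed a rule fixed with the lists: Ep300 always; per comparison up to 10 rises and 10 falls, the largest among genes that passed, whose groups did not overlap and whose higher group mean was above the median level of all genes (8.57 log2); up to 4 passing members of each list per direction and up to 2 that did not pass; and 5 genes with the smallest p where the interaction called none. Genes named outside the rule are stated as such.

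The alternatives were the experiment as a fixed block or as a random effect, only the groups compared, dim genes left out (below the 30th percentile), every probe set, the mean of a gene's probe sets, quantile normalisation again, cyclic loess, arrays centred on their medians, eBayes without a trend or robust, array weights, and leaving out each array and each experiment in turn. The leave-outs were fitted without the block. The pipeline was tested on simulated data with 14507 genes, of which 200 changed by 1 or 0.5 log2 for each effect. Changes of 1 log2 were recovered in 97% of cases for Dox in NS cells, 97% for Dox in p300 siRNA cells, 96% and 97% for the siRNA at 0 h and 8 h, 99% for its average and 83% for the interaction. For changes of 0.5 log2 the shares were 64%, 70%, 59%, 60%, 88% and 23%. With the block more were recovered (85% of 0.5 log2 changes for the siRNA at 8 h, against 60%), but more unchanged genes were called too (33 of 408 calls there, against 4 of 331). For Dox these were 14 of 204 in NS cells (0 of 161 without the block) and 16 of 397 in p300 siRNA cells (0 of 334). For the siRNA at 0 h, its average and the interaction they were 6 of 196 (1 of 157), 22 of 395 (5 of 324) and 9 of 159 (1 of 107). In the simulated average comparison, a shift of -0.3 log2 given to the macrophage list was called by camera and 0 of the 24 other lists were. The simulated noise was independent between genes. It therefore does not show how often the set test calls lists whose members vary together.

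Dox and time cannot be separated, since no 8 h culture without drug is among the groups. Effects of the p300 siRNA that do not act through p300 cannot be separated either. No other p300 siRNA and no rescue is among the groups. Raw probe intensities were not used here, so background correction and summarisation could not be repeated.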

Results

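Transcript levels were measured on 12 Affymetrix whole-transcript arrays, 1 per culture of neonatal rat cardiac myocytes. The cells had received either a non-silencing siRNA (NS) or an siRNA against p300, the lysine acetyltransferase encoded by Ep300. Each kind was collected before doxorubicin (Dox, an anthracycline that inhibits topoisomerase II) and after 8 h in 1 µM Dox, which gave 4 groups of 3 arrays from 3 experiments. The comparisons ask which transcripts differ after the drug, which differ with less p300, and whether the drug response differs with less p300. The number of arrays limits the precision: the median standard error (SE) of a difference between 2 groups was 0.0951 on the log2 scale. Drug and time went together, since the 0 h cultures were the only untreated ones. The first principal component held 60.9% of the variance and parted the 8 h from the 0 h arrays, the next held 15.3% and followed the experiment, and a further 7.46% followed the siRNA.

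Ep300 itself (probe set 10897919) had a mean log2 intensity of 11.11 ± 0.0838 (SD, n = 3) in untreated NS cells and 10.16 ± 0.215 (SD, n = 3) in untreated p300 siRNA cells. After 8 h of Dox the means were 10.77 ± 0.0817 and 9.85 ± 0.233 (SD, n = 3 each). With the p300 siRNA Ep300 fell to 51.9% of its NS level at 0 h (log2 change -0.95, SE 0.126, adjusted p = 0.0404) and to 52.9% at 8 h (-0.92, SE 0.126, adjusted p = 0.0271). Averaged over both times the change was -0.93 (SE 0.0894, adjusted p = 0.00212), and it lay below 0 in 6 of 6 differences taken within an experiment, from -1.09 to -0.76. The call at 0 h was lost under 14 of the 27 alternatives and the call at 8 h under 12, in both cases without experiment 2 or 3, without any 1 NS array and when only the groups compared were fitted. The drug changed Ep300 by -0.34 in NS cells (adjusted p = 0.0641) and by -0.31 in p300 siRNA cells (adjusted p = 0.0782), and both passed with the experiment as a block (adjusted p = 0.00153 and 0.00249).

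**Figure D1:**
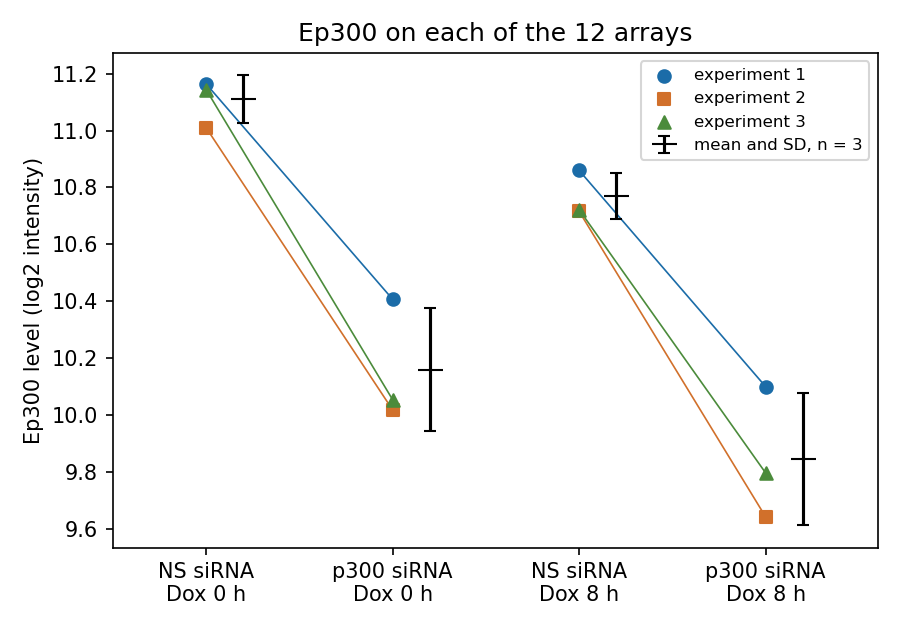
Ep300 level (log2 intensity, vertical axis) on each of the 12 arrays by group; marks and lines show the 3 experiments, black bars the mean and SD of 3 arrays. In each experiment the p300 siRNA array lay below the NS array at the same time, with differences from -1.09 to -0.76 log2.

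The largest falls after 8 h of Dox in NS cells included, among others, genes that are known from the heart. Depp1, a target of FOXO factors, fell 10.3-fold (log2 change -3.36, SE 0.175, adjusted p = 2.55e-07). Lmod2, which elongates the thin filament, fell 7.54-fold (-2.91, SE 0.202), and Lrrc10, a cardiac leucine-rich repeat protein, fell 6.81-fold (-2.77, SE 0.310). Nkx2-5, a homeobox factor of heart development, fell 6.20-fold (-2.63, SE 0.103, adjusted p = 4.27e-08), and Rrad, a small GTPase that restrains L-type calcium channels, fell 5.97-fold (-2.58, SE 0.165). The other large falls were in Gata5 (-2.39), Ccnf, which encodes cyclin F (-2.27), A4galt (-2.24), Shroom3 (-2.23) and Kcnj5, a subunit of the atrial acetylcholine-gated potassium channel (-2.21). Among the rises, Ppp2r2c, a regulatory subunit of protein phosphatase 2A, rose 4.14-fold (2.05, SE 0.0999, adjusted p = 2.04e-07). Pmaip1, which encodes the pro-apoptotic BH3 protein NOXA, rose 4.01-fold (2.00, SE 0.191, adjusted p = 1.25e-05). Il1rl2 (1.59), Itpka (1.57), Abcb1b, a P-glycoprotein that exports drugs including doxorubicin (1.57, SE 0.157), Slc4a11 (1.55), Fam167a (1.54), Tshr (1.54) and Ankrd13d (1.53) also rose, as did Cfap141 (1.55), whose call was lost without experiment 2.

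Cardiac transcription factors fell as a group. Of 20 measured, 15 fell and 0 rose over all genes (16 fell adjusted over the list alone), with a median change of -1.09 that was -0.89, -1.07 and -1.27 in the 3 experiments. Within the list Nkx2-5, Irx4 (-1.75), Gata4 (-1.41) and Hey2 (-1.32) fell most, while Smyd1 (0.24) and Srf (-0.22) did not pass (adjusted p = 0.0207 and 0.00731 with the block). Gata5, named above, is not on the list. The set test gave an adjusted p of 1.59e-12, and adjusted p = 0.161 with an estimated correlation. Of the 19 genes of the sarcomere list, which encode contractile filaments and do not include Lmod2 (-2.91), 0 passed, over all genes and adjusted over the list alone (median 0.02, set test adjusted p = 0.663). Their values included Tnni1 at 0.22 (adjusted p = 0.000897 with the block) and Csrp3 at -0.12. Of 22 calcium handling and ion channel genes 4 fell by both adjustments, among them Cacnb2, a calcium channel subunit (-2.03), Gja5, which encodes connexin 40 (-0.97), and Kcnj2 (-0.93; lost without experiment 2), with a set test adjusted p of 0.232; the experiment as a block gave 6 rising and 8 falling. Of 10 hypertrophy-associated genes 4 fell by both adjustments, led by Rcan1, a calcineurin target (-1.89), and Ccn2 (-1.34). Their set test gave adjusted p = 0.0601, or 0.0321 with the experiment as a block, lost with the block and an estimated correlation (adjusted p = 0.652). With fry the hypertrophy-associated genes were called lower (adjusted p = 0.0244). Nppa (0.10) and Nppb (-0.16), which encode the natriuretic peptides, did not pass (Nppa at adjusted p = 0.0268 with the block).

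p53 target genes mostly rose with the drug in NS cells: of 24 measured, 13 rose and 3 fell (14 and 3 adjusted over the list alone; median 0.42). Pmaip1 (2.00), Gdf15, a stress-induced secreted factor (1.19), and Mdm2, the ligase that degrades p53 (0.72; lost without experiment 2), rose, and so did the cell cycle inhibitor Cdkn1a (0.68, named after its value was seen). Sesn1 (-0.99), Ppm1d (-0.61) and Gadd45a (-0.40; lost without experiment 1, 2 or 3), also targets of p53, fell. Their set test gave 0.00283, and adjusted p = 0.687 with an estimated correlation. Of 26 BCL2 family and apoptosis genes 8 rose and 7 fell (10 and 8 adjusted over the list alone), with the pro-apoptotic Pmaip1 and Bax (0.46; lost without experiment 2) among the rises and the anti-apoptotic Mcl1 (-0.76) beside the initiator caspase gene Casp9 (-0.65) among the falls (set test adjusted p = 0.875). Cytokine and NF-kB genes rose in 7 of 19 cases and fell in 1, by both adjustments (median 0.30). The interleukin gene Il6 (1.42), the adhesion molecule gene Icam1 (1.07) and Lif (0.94) rose, and Nfkb1 fell (-0.34; lost without experiment 2 or 3). The set test adjusted p was 0.00875 and rose to 0.209 without replicate 2 of the 8 h NS group; it was adjusted p = 0.818 with an estimated correlation. Immediate early genes split, with 7 rising and 8 falling of 22 (8 and 8 adjusted over the list alone; set test adjusted p = 0.875). Fosl1 (1.45), Egr2 (1.06) and Egr3 (0.91) rose, while Ier3 (-1.22), Jun (-1.13) and Dusp1 (-0.92) fell.

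Cell cycle genes fell in 10 of 25 cases and rose in 1 in the treated NS cells (12 and 2 adjusted over the list alone; median -0.36). Cdc20 (-1.63), Plk1 (-1.36), Ccnb1 (-1.26) and Bub1b (-1.16), all of mitosis, fell, and Tyms, of thymidylate synthesis, rose (0.77). Top2a, which encodes the topoisomerase II isoform of dividing cells, fell by 0.51; it was named after its value was seen, and its call was lost without experiment 1 or 3 and without any of 4 single arrays. As a set they had an adjusted p of 8.90e-04, and adjusted p = 0.687 with an estimated correlation. Of 20 replication-dependent histone genes 12 fell and 2 rose (14 and 3 adjusted over the list alone; median -0.58). H1f4 (-1.60) and H4c14 (-1.30) fell and H2ac25 (1.02) rose, with a set test adjusted p of 5.70e-04 and adjusted p = 0.687 with an estimated correlation. Acetyltransferase and deacetylase genes, a list that includes Ep300, fell in 13 of 27 cases and rose in 2 (15 and 4 adjusted over the list alone, median -0.30). The acetyltransferase genes Kat7 (-1.17), Kat5 (-0.93) and Kat2a (-0.66) and the coactivator gene Ncoa1 (-0.55) fell most. The set test adjusted p was 0.0142, was 0.0872 without the dim genes, and was adjusted p = 0.161 with an estimated correlation. TGF-beta and SMAD target genes fell in 9 of 17 cases by both adjustments (median -0.39), among them Ccn2 (-1.34), Smad6, an inhibitory SMAD (-1.31), and the matricellular gene Ccn1 (-0.82). Their set test adjusted p was 0.00111, and adjusted p = 0.687 with an estimated correlation.

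Oxidative phosphorylation genes rose in 3 of 26 cases (2 adjusted over the list alone; median 0.18), among them Ndufb8, of complex I (0.48; lost without experiment 2). With the experiment as a block 24 rose. Their set test adjusted p was 0.00221 (0.0508 without replicate 3 of the 8 h NS group), and adjusted p = 0.818 with an estimated correlation. Of 22 fatty acid oxidation genes 2 rose and 3 fell by both adjustments, with the coactivator genes Ppargc1b (-1.35) and Ppargc1a (-1.22; lost without experiment 2) and the carnitine palmitoyltransferase gene Cpt1a (-0.92) falling; the block gave 16 rising and 3 falling and moved the set test from an adjusted p of 0.236 to 0.00704, which was lost with the block and an estimated correlation (adjusted p = 0.652). Antioxidant and NRF2 target genes rose in 4 of 21 cases and fell in 3 (5 and 3 adjusted over the list alone; set test adjusted p = 0.155), with Sod2 (0.50) and Srxn1 (0.42) rising and the metallothionein gene Mt1 (-0.51) falling. The calls of Sod2 and Mt1 were lost without experiment 2 or 3 and that of Srxn1 without experiment 3, while the block gave 11 rising and 3 falling in the list. With fry this list was called higher (adjusted p = 0.0133) and heat shock and unfolded protein genes lower (adjusted p = 0.0161). Of 17 heat shock and unfolded protein genes 5 fell by both adjustments, led by Xbp1 (-1.03) and Dnajb1 (-0.86; set test adjusted p = 0.198). Of 22 DNA repair genes 1 rose, Xrcc1 (0.49), and 3 fell, among them Brca2 (-0.57; lost without experiment 3), by both adjustments (set test adjusted p = 0.663). The block gave 6 and 5, and Lig4, at 1.04, did not pass (adjusted p = 0.0770, or 2.83e-05 with the block). Of 22 HIF target genes 1 rose and 2 fell (0 and 2 adjusted over the list alone, 8 and 3 with the block; set test adjusted p = 0.600). Of 24 interferon response genes 3 rose and 1 fell by both adjustments, with Gbp2 (0.85) and Tap1 (0.84) rising and Irf9 (-0.93) falling. Their set test adjusted p was 0.230, or 0.0347 with the experiment as a block, which gave 10 rising and 3 falling; with the block and an estimated correlation that call was lost (adjusted p = 0.737).

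The medians of the marker lists in treated NS cells were 0.04 for 19 fibroblast markers, -0.05 for 11 endothelial markers, -0.07 for 11 smooth muscle and pericyte markers, 0.07 for 14 macrophage and leukocyte markers, 0.19 for 5 erythroid markers and 0.06 for 10 cardiac myocyte markers, and no set test passed (adjusted p from 0.230 to 0.663). fry called endothelial markers lower (adjusted p = 7.13e-04) and erythroid markers higher (adjusted p = 0.0161). Single receptors fell: Pdgfra of fibroblasts (-0.79), Kdr of endothelium (-0.92), Cspg4 (-1.09) and Pdgfrb (-0.85; lost without experiment 2 or 3) of pericytes and Csf1r of macrophages (-0.54). The counts by both adjustments were 1 up and 1 down for fibroblast, 2 down for endothelial, 4 down for smooth muscle and pericyte, 1 down for macrophage, 1 up for erythroid and 0 for myocyte markers. The block gave 4 up and 3 down for fibroblast, 2 and 4 for endothelial, 3 and 4 for smooth muscle and pericyte, 3 and 2 for macrophage and 2 and 0 for erythroid markers.

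In all, 3993 of 14507 genes passed in NS cells at an adjusted p under 0.05, 1618 up and 2375 down, of which 57 rose and 197 fell at least 2-fold. The change had 1 sign in all 3 experiments for 3988 of them (99.9%, against 64.7% of all genes), which largely follows from selecting them on the same arrays. The 3 arrays of a group lay wholly above or below the other 3 for 5995 genes, which chance gives for 10% of genes. With the experiment as a block 6318 passed (3134 up, 3184 down), and without experiment 2 or 3 the number was 1780 or 1937. The split between rises and falls depended on the scaling: with each array centred on its median, which moved the median change of all genes from 0.0362 to 0.138, 3787 rose and 1832 fell. Changes of about 0.1 log2 are therefore relative to that choice, while no named gene that passed turned its direction.

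**Figure D2:**
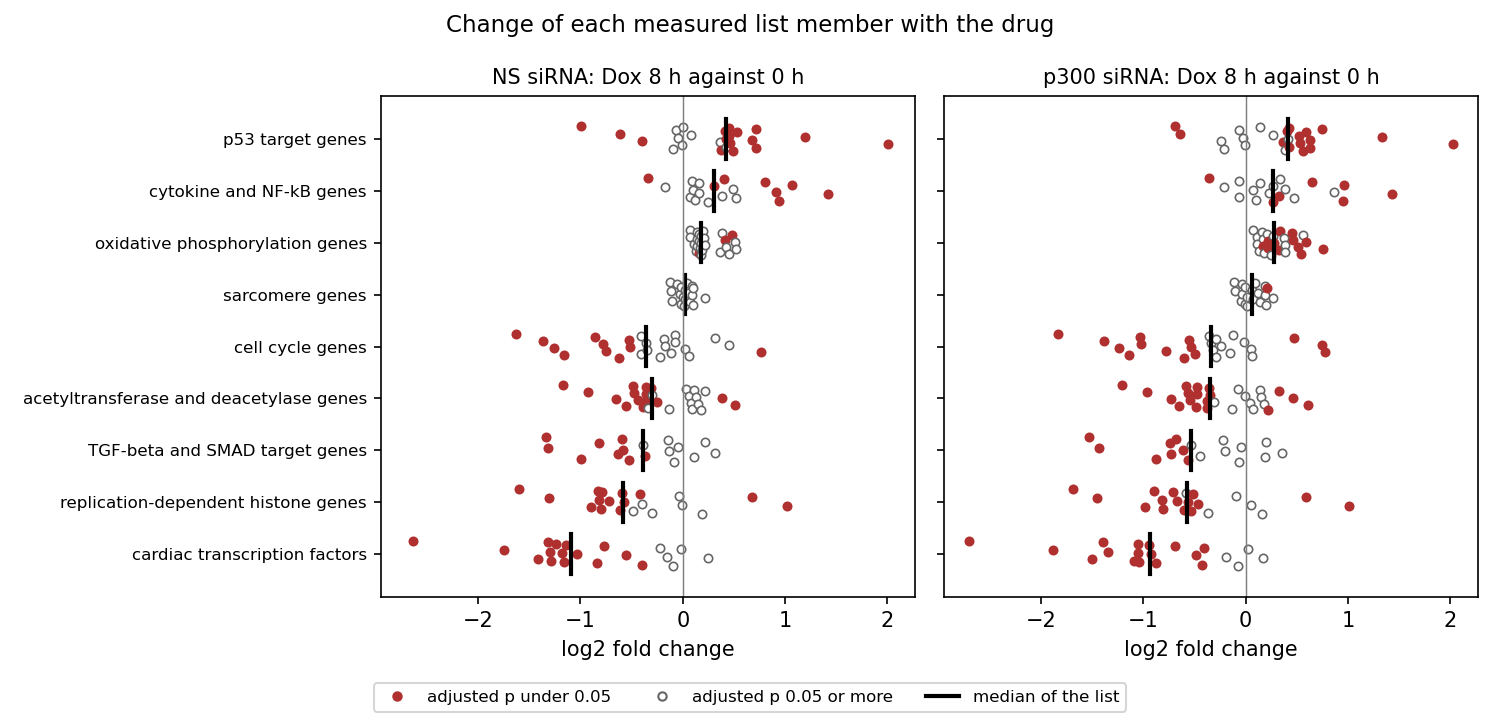
Log2 fold change after 8 h of Dox (horizontal axis) for each measured member of 9 gene lists, in NS cells on the left and p300 siRNA cells on the right; filled points passed and black lines are list medians. Cardiac transcription factors had medians of -1.09 and -0.93, while sarcomere genes lay near 0 (0.02 and 0.06).

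The same drug in p300 siRNA cells lowered Rrad 10.3-fold (log2 change -3.36, SE 0.165, adjusted p = 1.51e-07), Depp1 8.86-fold (-3.15), Lmod2 8.27-fold (-3.05) and Nkx2-5 6.54-fold (-2.71). B3galt2, a galactosyltransferase (-2.59), Lrrc10 (-2.62), Gata5 (-2.29), Ccnf (-2.27), Dlc1 (-2.17) and Shroom3 (-2.15) completed the 10 largest falls. Pmaip1 rose 4.08-fold (2.03, SE 0.191, adjusted p = 9.18e-06) and Ppp2r2c 3.84-fold (1.94), followed by Cfap141 (1.80), Abcb1b (1.75), the AP-1 subunit gene Fosl1 (1.69), Hspa2, an HSP70 family chaperone (1.65), Fam167a (1.62), Il1rl2 (1.61), Cib2 (1.57) and Nptx2 (1.54). Cardiac transcription factors again fell, 16 of 20 (17 adjusted over the list alone; median -0.93, set test adjusted p = 1.76e-11), among them Irx4 (-1.88), Gata4 (-1.50) and the SRF coactivator gene Myocd (-1.40). That call was lost as adjusted p = 0.170 with an estimated correlation. Of 19 sarcomere genes 1 rose, Tnnc1 (0.21), and 0 fell (0 and 0 adjusted over the list alone). The median was 0.06, the set test adjusted p was 0.358, and the call of Tnnc1 was lost under 10 of the alternatives, while 7 members rose with the experiment as a block.

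Among the p53 target genes of p300 siRNA cells 13 of 24 rose and 2 fell (16 and 3 adjusted over the list alone), with Pmaip1, Gdf15 (1.33) and Mdm2 (0.74) rising. Together they gave a set test adjusted p of 0.00191, and adjusted p = 0.675 with an estimated correlation. Oxidative phosphorylation genes rose in 12 of 26 cases by both adjustments (24 with the experiment as a block), with a set test adjusted p of 4.13e-04 and adjusted p = 0.828 with an estimated correlation. Ndufa10 of complex I (0.75) was among them, and its call was lost without experiment 2 or 3. Of the 19 cytokine and NF-kB genes 6 rose and 1 fell (8 and 1 adjusted over the list alone), with Il6 at 1.43 and Icam1 at 0.96. The set test adjusted p was 0.0391, was above 0.05 under 8 alternatives, and was adjusted p = 0.828 with an estimated correlation. Cell cycle genes fell in 11 of 25 cases and rose in 3 (13 and 3 adjusted over the list alone), with Cdc20 at -1.83 and Ccnb1 at -1.39, a set test adjusted p of 7.68e-04 and adjusted p = 0.675 with an estimated correlation. Of 20 histone genes 13 fell and 2 rose (15 and 2 adjusted over the list alone), with H1f4 at -1.69, a set test adjusted p of 4.13e-04 and adjusted p = 0.675 with an estimated correlation. Of 27 acetyltransferase and deacetylase genes 14 fell and 4 rose (15 and 4 adjusted over the list alone), with Kat7 at -1.21 and Kat5 at -0.97; the set test adjusted p was 0.00653, was 0.0551 without the dim genes, and was adjusted p = 0.170 with an estimated correlation. TGF-beta and SMAD target genes fell in 8 of 17 cases (9 adjusted over the list alone), with Ccn2 at -1.53 and Smad6 at -1.43, a set test adjusted p of 0.00130 and adjusted p = 0.675 with an estimated correlation. Of 10 hypertrophy-associated genes 3 fell (4 adjusted over the list alone), among them Rcan1 (-1.99). Their set test gave 0.0305 and adjusted p = 0.822 with an estimated correlation. It was lost without the dim genes, without replicate 1 of the 0 h and without replicate 3 of the 8 h p300 siRNA group (0.112 at most), and the block gave 6 falls.

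The remaining pathway lists of p300 siRNA cells had no set test that passed with the drug. Among them fry called antioxidant and NRF2 target genes higher (adjusted p = 0.00383) and heat shock and unfolded protein genes lower (adjusted p = 0.0156). Fatty acid oxidation genes rose in 7 of 22 cases and fell in 3 (11 and 3 adjusted over the list alone), with a set test adjusted p of 0.160, or 0.00152 with the experiment as a block (16 up, 3 down), lost with the block and an estimated correlation (adjusted p = 0.624). Ppargc1b (-1.39) and Cpt1a (-1.19) fell. Antioxidant and NRF2 target genes rose in 7 of 21 cases and fell in 2 (9 and 3 adjusted over the list alone, 12 and 3 with the block), with Sod2 at 0.74. Of 22 immediate early genes 6 rose and 8 fell, with Fosl1 (1.69), Egr2 (1.48) and Egr1 (0.77) rising and Ier3 (-1.25) and Dusp1 (-1.22) falling. The counts up and down were 8 and 8 for BCL2 family and apoptosis genes, 4 and 4 for DNA repair genes (7 and 5 with the block), 1 and 5 for calcium handling and ion channel genes (5 and 9), 1 and 6 for heat shock and unfolded protein genes (5 and 7), 4 and 1 for HIF target genes (7 and 5) and 2 and 1 for interferon response genes (6 and 7). Among the cell type lists the medians were 0.11 for macrophage and leukocyte, 0.11 for fibroblast, -0.02 for endothelial, -0.11 for smooth muscle and pericyte, 0.09 for erythroid and 0.08 for myocyte markers, with set test adjusted p from 0.205 to 0.694. As in NS cells, fry called endothelial markers lower (adjusted p = 5.22e-04) and erythroid markers higher (adjusted p = 0.0215). In all, 4561 genes passed, 2018 up and 2543 down, of which 56 rose and 233 fell at least 2-fold. The block gave 6644 (3331 up, 3313 down). Without experiment 2 or 3 the number was 2270 or 2361, and with each array centred on its median, which moved the median change of all genes from 0.0409 to 0.145, 4344 rose and 1996 fell.

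Set side by side, the drug responses of NS and p300 siRNA cells correlated across genes (Pearson r = 0.946, Spearman correlation 0.884; genes are not independent replicates). Both comparisons called 1272 genes up (225 if the calls were independent) and 2138 down (416 if independent), and 0 genes in opposite directions. The test of the difference itself called 0 of 14507 genes in limma, against 228 at an unadjusted p under 0.05, and 0 with the experiment as a block (639 unadjusted). Both unadjusted numbers are below the share of 0.05 of all genes that chance gives. Offsets of whole experiments cancel in this contrast but stay in the error of the model without the block (median SE 0.1345, or 0.111 with it). That test is therefore cautious, and its 0 calls do not show that no gene differed. The 5 genes with the smallest p were Cyp3a9 (-0.71, SE 0.148), Or52n1 (-0.46), Gpr65 (0.42), Prl3c1 (0.38) and Or5o1 (0.34), each with an adjusted p of 0.9998 and each dim (levels from 4.97 to 5.94, below the 30th percentile). Ep300 differed by 0.03 (adjusted p = 0.9998). For 5122 of the 5144 genes called in either comparison (99.6%) the 95% interval of the difference lay within 1 log2 of 0, and the median half-width was 0.291 over all genes. This bound is wide, since few called genes changed that much with the drug itself (57 up and 197 down of 3993 in NS cells). In the simulation 23% of interactions of 0.5 log2 were recovered, so smaller differences in the drug response could go uncalled. Among the lists, interferon response genes had a median change with the drug of 0.19 in NS and -0.10 in p300 siRNA cells (median difference -0.27 over 24 genes, set test adjusted p = 0.00676), with 0 members passing singly by either adjustment and Mx1 at -0.48 (SE 0.719) and Rsad2 at -0.47 (SE 0.687). That call was lost as adjusted p = 0.994 with an estimated correlation, and the medians within the 3 experiments were -0.44, -0.29 and 0.00466. It was also lost with array weights, without experiment 2, and without replicate 1 of the 0 h NS, 2 of the 0 h p300 siRNA, 2 of the 8 h NS or 1 of the 8 h p300 siRNA group (0.809 at most). With the experiment as a block the set test also called fatty acid oxidation genes (0.00656) and oxidative phosphorylation genes (5.73e-04), with median differences of 0.05 each. Both were lost with the block and an estimated correlation (adjusted p = 0.956 each), and the oxidative phosphorylation median was -0.03 in experiment 3.

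Before the drug, the p300 siRNA raised Nnat, the imprinted gene of neuronatin, 1.7-fold (log2 change 0.77, SE 0.0884, adjusted p = 0.0168). It lowered Igfbp5, a secreted binding protein of insulin-like growth factors, 1.53-fold (-0.61, SE 0.0861, adjusted p = 0.0444) besides Ep300, and these 3 were all that passed. At 8 h of Dox, 7 genes were lower with the p300 siRNA and 0 higher. They were Ep300, Dsc3, which encodes a desmosomal cadherin (-1.08, SE 0.166, adjusted p = 0.0486), the keratin gene Krt19 (-0.70, SE 0.107, adjusted p = 0.0486), Gas7 (-0.59, SE 0.0852, adjusted p = 0.0379) and, named after their values were seen, B3galt2 (-1.001), Cyp3a9 (-0.83) and Cd7 (-0.75; adjusted p = 0.0187 each). Cyp3a9 is dim (level 5.92, below the 30th percentile of all genes). At 8 h Nnat was at 0.45 (adjusted p = 0.194) and Igfbp5 at -0.49 (adjusted p = 0.111), and both passed with the experiment as a block. The changes at 0 h and 8 h correlated across genes (Pearson r = 0.606, Spearman correlation 0.463); genes are not independent replicates.

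Macrophage and leukocyte markers were lower with the p300 siRNA at both times. Their median was -0.32 at 0 h (set test adjusted p = 5.84e-10; adjusted p = 0.196 with an estimated correlation) and -0.31 at 8 h (5.65e-10; adjusted p = 0.217 with an estimated correlation). Over all genes 0 of 14 passed at either time, while 7 fell at 0 h and 5 at 8 h adjusted over the list alone, and 6 and 7 with the experiment as a block. Beside them, cytokine and NF-kB genes had medians of -0.16 and -0.29, antioxidant and NRF2 target genes of -0.13 and -0.09, and fibroblast markers of -0.10 and -0.16. Their set tests gave adjusted p of 1.23e-04 and 3.38e-06, 1.41e-06 and 9.94e-04, and 2.16e-05 and 3.40e-05. These became adjusted p = 0.666 and 0.728, 0.0641 and 0.217, and 0.201 and 0.217 with an estimated correlation. The cytokine call at 8 h was also lost without replicate 2 of the 8 h NS group (0.0794). Interferon response genes had a median of 0.19 at 0 h (set test adjusted p = 0.00755; adjusted p = 0.743 with an estimated correlation) and -0.04 at 8 h (0.622), and the call at 0 h was also lost without replicate 1 of the NS or 2 of the p300 siRNA group (0.611 at most). Replication-dependent histone genes had medians of 0.15 and 0.10 (4.91e-05 and 0.00655; adjusted p = 0.666 and 0.755 with an estimated correlation), and the call at 8 h was lost under 4 alternatives besides. Other lists that the set test called lower at both times were endothelial markers (medians -0.14 and -0.11; 0.0240 and 0.0319), calcium handling and ion channel genes (-0.12 and -0.16; 0.0166 and 0.00629), heat shock and unfolded protein genes (-0.05 and -0.05; 0.0256 and 0.0333) and TGF-beta and SMAD target genes (-0.08 and -0.08; 0.0338 and 0.0249). Cardiac transcription factors (0.0473) and fatty acid oxidation genes (0.0240) were called at 0 h alone. Each of these was lost under at least 3 alternatives as well as with an estimated correlation (adjusted p from 0.196 to 0.755 with an estimated correlation). With the block, sarcomere (0.0359), oxidative phosphorylation (0.0123) and HIF target genes (0.0223) were called at 0 h too, and all 3 were lost with the block and an estimated correlation (adjusted p = 0.595, 0.595 and 0.459). The block also gave single-gene falls at 0 h and 8 h in the fibroblast (5 and 4), cytokine and NF-kB (4 and 4) and antioxidant lists (4 and 5), and 4 rises of interferon response genes at 0 h. The single-gene calls changed with the arrays used: without experiment 2 or 3, 0 genes passed at either time, and without experiment 1, 20 passed at 0 h and 17 at 8 h. No leave-out was fitted with the experiment as a block. Whether these losses come from few arrays or from ignoring the experiment was not tested. With the experiment as a block 390 genes passed at 0 h (101 up, 289 down) and 457 at 8 h (113 up, 344 down). At an unadjusted p under 0.05 there were 1008 and 1156 genes. The 3 arrays of a group lay wholly above or below the other 3 for 1888 of 14507 genes at 0 h and 1604 at 8 h, where chance gives 10% of genes if the 6 arrays are interchangeable. They are not, since arrays of 1 experiment vary together, so that 10% is not an exact reference.

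Averaged over 0 h and 8 h, the p300 siRNA lowered Chi3l1, a secreted chitinase-like protein, 2.19-fold (log2 change -1.13, SE 0.174, adjusted p = 0.0170). Other falls were in Ly6c (-0.81), the adhesion receptor gene Adgrg1 (-0.81, SE 0.0933, adjusted p = 0.00292), Hsd11b1, which regenerates active glucocorticoid (-0.76), Akr1b8 (-0.73), Ggt1, of glutathione breakdown (-0.73), the secreted phospholipase gene Pla2g2d (-0.70), Lbp, which encodes a lipopolysaccharide-binding protein (-0.69), and the kinase gene Map4k4 (-0.69). Fewer and smaller changes went up: the imprinted non-coding RNA H19 (0.57, SE 0.101, adjusted p = 0.0245), the synaptic adhesion gene Nlgn2 (0.34), the cytokine gene Ctf1 (0.32), Amd1, of polyamine synthesis (0.32), the histone gene Hist3h2ba (0.27) and Ssh3 (0.26). The calls of Hist3h2ba and Ssh3 were lost with each of the 3 other scalings of the arrays. Nnat (0.61) and Igfbp5 (-0.55, adjusted p = 0.00292) passed as well. Crebbp, the closest relative of Ep300, was at 0.04 (SE 0.0634, adjusted p = 0.887). In all 181 genes passed, 33 up and 148 down.

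Macrophage and leukocyte markers were again lower: 5 of 14 fell over all genes and 10 adjusted over the list alone or with the block (median -0.29). Mrc1 (-0.51), Csf1r (-0.46), Tyrobp (-0.43) and Ptprc (-0.40) were among the falls. Fcgr2b (-0.70) and Cd68 (-0.39) did not pass (adjusted p = 6.16e-05 and 5.69e-04 with the block). The set test adjusted p was 3.70e-12, and adjusted p = 0.113 with an estimated correlation. Fibroblast markers fell in 1 of 19 cases, Fbln1 (-0.34), and in 5 adjusted over the list alone (median -0.12, set test adjusted p = 9.45e-07, adjusted p = 0.120 with an estimated correlation; 11 fell with the block). Endothelial markers had a median of -0.06 (0 and 2 falls; set test adjusted p = 0.00742, adjusted p = 0.113 with an estimated correlation). Smooth muscle and pericyte markers had a median of -0.01 (1 fall, Cspg4 at -0.37; adjusted p = 0.319), cardiac myocyte markers of -0.05 (0 falls; 0.204) and erythroid markers of -0.03 (0.369). Cytokine and NF-kB genes fell in 2 of 19 cases, the monocyte chemoattractant genes Ccl7 (-0.67) and Ccl2 (-0.57), and in 6 adjusted over the list alone or with the block. Their median was -0.22, beside the -0.29 of the macrophage markers, with a set test adjusted p of 9.45e-07 and adjusted p = 0.569 with an estimated correlation. Antioxidant and NRF2 target genes fell in 0 of 21 cases over all genes and in 6 adjusted over the list alone (9 with the block), with a median of -0.10, a set test adjusted p of 1.28e-06 and adjusted p = 0.0723 with an estimated correlation. Nqo1 was at -0.45 (adjusted p = 0.152, or 5.66e-04 with the block).

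**Figure D3:**
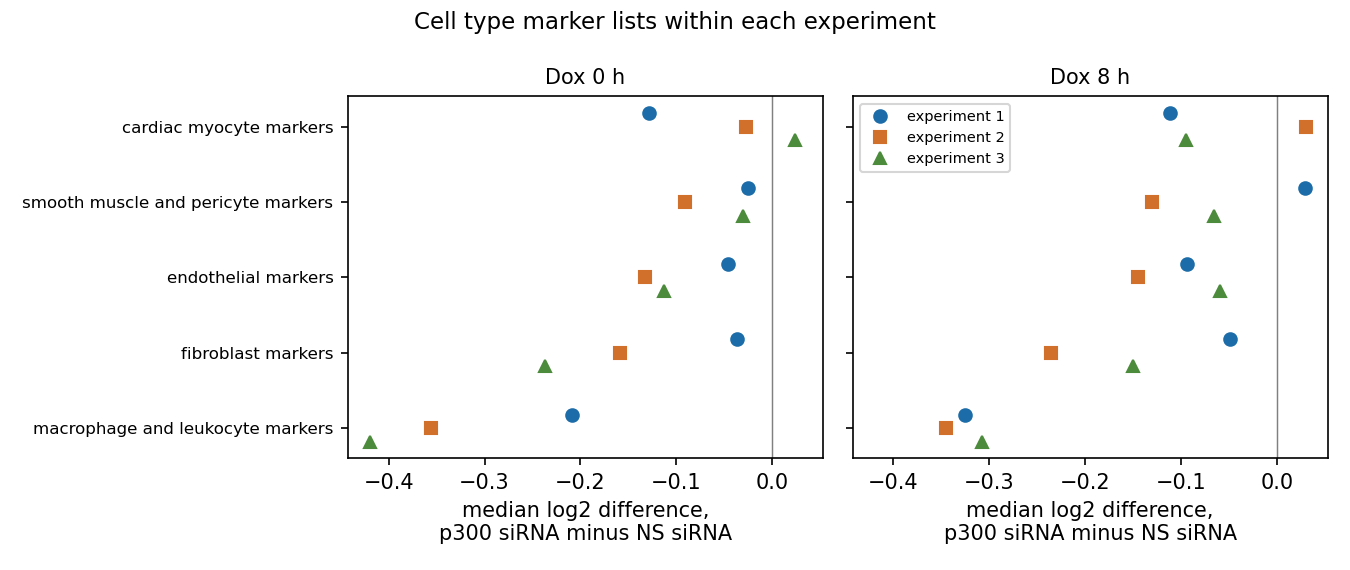
Median log2 difference between p300 siRNA and NS arrays (horizontal axis) of 5 marker lists within each of the 3 experiments, at 0 h and 8 h of Dox. The macrophage and leukocyte medians lie between -0.42 and -0.21 in all 6 differences.

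The remaining pathway lists had medians between -0.12 and 0.13 with the average knockdown. Replication-dependent histone genes had a median of 0.13, with 1 of 20 rising by both adjustments (set test adjusted p = 6.08e-05, adjusted p = 0.597 with an estimated correlation; 7 rose with the block). Calcium handling and ion channel genes had a median of -0.12 with 0 of 22 passing, or 4 falling with the block (0.00141, adjusted p = 0.602 with an estimated correlation), a call that was lost without experiment 1 or replicate 1 of the 8 h p300 siRNA group (0.0809 at most). TGF-beta and SMAD target genes had a median of -0.08 with 1 of 17 falling, Tgfbi at -0.71, and 2 adjusted over the list alone or 5 with the block (0.00858, adjusted p = 0.602 with an estimated correlation; lost without experiment 2, replicate 2 of the 0 h p300 siRNA, 1 of the 8 h NS or 3 of the 8 h p300 siRNA group, 0.276 at most). Heat shock and unfolded protein genes had a median of -0.06 (0.00841, adjusted p = 0.569 with an estimated correlation), as had cardiac transcription factors (0.0354, adjusted p = 0.653 with an estimated correlation), with 0 members passing in each, or 4 and 2 falling with the block. The former call was lost without experiment 2 and without replicate 2 of either NS group (0.425 at most), the latter under 10 alternatives (0.540 at most). p53 target genes (-0.00162), sarcomere genes (-0.03) and oxidative phosphorylation genes (-0.01) had medians near 0 and no set test that passed. The same held for hypertrophy-associated (-0.04), immediate early (-0.02), DNA repair (0.04) and HIF target genes (-0.03), for BCL2 family and apoptosis genes (1 fall, Bok at -0.31), cell cycle genes (1 fall, Ccnd1 at -0.38) and acetyltransferase and deacetylase genes (1 fall, Ep300). With the experiment as a block the set test also called fatty acid oxidation (0.00470) and interferon response genes (0.00470), of which 2 and 0 had passed singly without it (4 falls and 2 rises with it). Both were lost with the block and an estimated correlation (adjusted p = 0.551 and 0.553).

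The number of genes in the averaged comparison depends on single arrays and on the experiment. It was 1381 with the experiment as a block (469 up, 912 down, all 181 among them), 372 without experiment 1 and 0 without experiment 2 or 3. Leaving out 1 NS array of 0 h gave 104, 37 or 30 genes for replicates 1 to 3, and leaving out replicate 2 or 3 gave 18 or 53 in the 8 h NS group, 7 or 38 in the 0 h p300 siRNA group and 73 or 52 in the 8 h p300 siRNA group. Without replicate 1 the number was 167 for the 8 h NS, 259 for the 0 h p300 siRNA and 211 for the 8 h p300 siRNA group. None of these leave-outs used the block. Of the 31 named genes that passed, Ep300, Nnat, Adgrg1 and Igfbp5 passed without any 1 array, and 0 of the 31 passed without experiment 2 or 3.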

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

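Of the tests reported here, that of an equal loss of non-myocytes of every kind, both tests of the interferon genes and both of the sarcomere genes were chosen only after the result was seen.

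Probe sets that do not carry exactly 1 gene symbol were left out of the comparisons, and a signal appeared there: of 13904 such probe sets, 1768 passed with Dox in NS cells (855 up, 913 down), 2610 with Dox in p300 siRNA cells (1542 up, 1068 down) and 20 with the averaged p300 siRNA (0 up, 20 down). The interferon response genes had a median difference between siRNAs in their drug response of -0.27, with 0 of 24 members passing and the set test lost with an estimated correlation (adjusted p = 0.994).

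The interferon difference came from medians with the drug of 0.19 in NS and -0.10 in p300 siRNA cells. An offset of whole experiments cancels in this contrast, so the block does not test it. The medians within the experiments were -0.44, -0.29 and 0.00466, and since 1 experiment gives no spread, a difference between experiments in the effect itself stays open. Interferon genes varying together from array to array also stay open, since the block with an estimated correlation gave an adjusted p of 0.794. An effect of p300, which the groups name, was not separated from these.

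Macrophage and leukocyte markers were lower with the p300 siRNA. A separate list of 36 other macrophage genes, written before its values were seen, had a median change of -0.244, with 97.2% below 0 and all 6 within-experiment medians between -0.352 and -0.14; its brightest members were Lgals3 (level 11.96, change -0.36), Arhgdib (11.52, -0.16), Fcer1g (11.02, -0.29) and Cybb (10.59, -0.47). Of these 36 genes 12, and of the 14 fixed markers 6, lay above the median level of all genes. The median of smooth muscle and pericyte markers lay 0.275 above that of macrophage markers (two-sided permutation test, p = 0.0045, adjusted p = 0.0090). The fibroblast median lay 0.166 above the macrophage median (two-sided permutation test, p = 0.0091, adjusted p = 0.0091). These 2 tests, adjusted together, permuted list members as independent replicates, so they do not cover variation between cultures. In each experiment, at both times, both medians lay above the macrophage median. They ran from -0.13 to 0.03 for smooth muscle and pericyte and -0.24 to -0.04 for fibroblast markers, against -0.42 to -0.21 for macrophage markers. An equal fall of these lists is argued against. Whether only the named cells make these markers was not tested, so an equal loss of non-myocytes of every kind is not excluded. A smaller loss of fibroblasts (median -0.12, 18 of 19 below 0) and endothelial cells (-0.06, 11 of 11 below 0) stays open. Fewer macrophages in the p300 siRNA cultures could give these values. A uniform effect of the p300 siRNA, through p300 or not, in an unchanged number of macrophages cannot be told apart from that. The changes of the 12 brighter genes spread by 1.64 times their median SE, below the ratio of 2 set beforehand for an uneven effect. That SE comes from the model without the block. The ratio therefore does not show that the changes were uniform, and an uneven effect stays open.

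The 19 genes of the sarcomere list did not pass with Dox in NS cells while cardiac transcription factors fell, as did the thin-filament gene Lmod2 outside the list (-2.91). Loss of myocytes as the cause of both would raise the markers of other cells. The medians of fibroblast (0.04) and macrophage (0.07) markers argue against a large loss. The myocyte markers had a median change of 0.0580, but most of them are also on the sarcomere list. That median mostly repeats the sarcomere result and is not separate evidence. The myocyte markers are bright, with sarcomere genes at a median level of 12.97, so saturation could hide part of a decrease. Of 232 genes at or above that level, 4 passed with a change of 0.5 log2 or more, all falling, which is too few to decide, and saturation cannot be told apart from stable transcripts of the listed genes. No biological explanation was tested.

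Other splits of the same arrays gave fewer genes in most cases. For 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real values were 3993 (highest other split 0) for Dox in NS cells, 4561 (0) for Dox in p300 siRNA cells, and 3 (0) and 7 (0) for the p300 siRNA at 0 h and 8 h, each reached by 1 of 10 splits. For the interaction, the 6 drug differences within experiments were split 3 against 3 in a separate fit. All 10 of these splits, the real one among them, gave 0 genes, which decides nothing. For the averaged p300 siRNA, 2 of 100 splits balanced for the drug gave 181 genes or more. The other one gave 1683 and set all 4 arrays of experiment 1 with the NS arrays of experiment 2 against the rest, so it follows the experiments and points to a structure of the samples. With the experiment as a block, 1 of the 32 splits that part all 6 same-experiment pairs, the real one, reached its 1381 genes, and the highest other gave 1. The 0 h and 8 h pairs of an experiment are not independent of each other. Splits by whole experiments are too few with 3 experiments, so chance cannot be excluded there.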

How the results depend on the processing

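Set tests with the block combined with an estimated correlation, or with fry, were chosen after seeing the data; the other alternatives were not. No result reversed. Against main counts of 3993, 3, 7 and 181 for Dox in NS cells and the p300 siRNA at 0 h, at 8 h and averaged, the experiment as a fixed block gave 6318, 390, 457 and 1381 genes, and as a random effect (correlation 0.317) 125, 92 and 818 for the last 3. Only the groups compared gave 0 and 0 at 0 h and 8 h, with fewer arrays behind the variance. Dim genes left out gave 4 at 8 h (Cyp3a9 is removed; Dsc3 and Krt19 lost their calls), cyclic loess 1 at 0 h, and array weights 139 at 0 h and 494 averaged; the cause of the latter 2 was not tested. Every probe set gave 7129 for Dox in p300 siRNA cells (4561 before), 0 at 0 h, 0 at 8 h and 59 averaged, over more tests. With an array or experiment left out, which leaves fewer arrays, the counts ran from 1780 to 4267 for Dox in NS cells, 2270 to 4848 in p300 siRNA cells, 0 to 20 at 0 h, 0 to 17 at 8 h and 0 to 372 averaged; the interaction stayed at 0 in every alternative. Of 332 named results of single genes, 49 lost their call with every probe set; with the block 0 lost and 28 gained one, and with the random effect 0 and 22. Leaving out arrays or experiments ended a call in 725 of the repeats and made one in 24, with 4231 on the same side. Of 49 list calls, 49 were lost with an estimated correlation, with or without the block, 31 with fry and 24 with fry and the block. Arrays centred on their medians kept each total within 1.5 times, though with more rises with Dox (3787 against 1618 in NS cells), and 47 of 49 list calls. Dim probe sets near background and very bright ones limit small changes.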

Other observations

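The tests of the lists in the next paragraph, and that of the drug against the knockdown, were chosen only after the result was seen.

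Gene families outside the fixed lists also moved with Dox. In NS cells 87 of 152 zinc finger genes named Zfp or Znf, mostly transcription factors, fell and 4 rose (median -0.37; set test adjusted p = 7.37e-16; adjusted p = 0.0567 with an estimated correlation), and in p300 siRNA cells 89 fell and 4 rose (median -0.41). Circadian clock genes fell in 8 of 15 cases and rose in 0 in NS cells (median -0.33; adjusted p = 2.18e-04; adjusted p = 0.213 with an estimated correlation), and in 7 cases with 2 rises in p300 siRNA cells (median -0.29). Ribosomal protein genes rose in 19 of 80 cases and fell in 0 in NS cells (median 0.15; adjusted p = 5.20e-07; adjusted p = 0.349 with an estimated correlation; 49 rose with the experiment as a block), and in 39 cases with 1 fall in p300 siRNA cells (median 0.18). With the averaged p300 siRNA their median was 0.08 with 0 of 80 passing, or 17 rising and 1 falling with the block (adjusted p = 7.01e-13; adjusted p = 0.173 with an estimated correlation), and the difference between the drug responses had a median of 0.06 with 0 passing (adjusted p = 0.00163; adjusted p = 0.833 with an estimated correlation). Proteasome subunit genes (3 up and 4 down of 39, median 0.05), homeobox and forkhead genes (13 up and 14 down of 82, median 0.05) and olfactory receptor genes, which heart cells should express little (17 up and 2 down of 1105, median 0.04), were not called as groups in NS cells. In p300 siRNA cells 7 proteasome subunit genes rose and 4 fell, 15 homeobox and forkhead genes rose and 14 fell, and 48 olfactory receptor genes rose and 1 fell (median 0.06; adjusted p = 0.0209; adjusted p = 0.431 with an estimated correlation). Proteasome subunit genes were also called with the averaged p300 siRNA (median 0.06, 0 passing; adjusted p = 0.00300; adjusted p = 0.563 with an estimated correlation).

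Nnat and H19, both imprinted, were higher with the p300 siRNA, which raised the hypothesis that imprinted genes rose as a group. The other 24 imprinted genes measured had a median change of 0.0338, below the 0.1 that the hypothesis needed. With Dox in NS cells the same 24 had a median of 0.18, with 3 rising and 2 falling (13 and 2 with the block). Their set test adjusted p there was 0.0455, and 0.213 with an estimated correlation. A like hypothesis for neuronal genes, from Nnat and Nlgn2, met a median of 0.0132 over 36 genes. Secreted defence genes among the largest falls raised the hypothesis that acute-phase and complement genes fell as a group: 21 had a median of -0.155 with 95.2% below 0, 1 falling singly (8 with the block), a set test adjusted p of 2.91e-07 and adjusted p = 0.0617 with an estimated correlation, beside the -0.29 of the macrophage and leukocyte markers. Such a decrease may follow the macrophage decrease or stand apart from it; these arrays do not separate the 2.

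That the p300 siRNA moves the genes the drug moves in a common direction was argued against by a correlation of the averaged responses across genes of 0.0640 (Spearman correlation 0.0684; genes are not independent replicates). Of 181 genes that passed with the averaged p300 siRNA, 108 (59.7%, against 45.1% of all genes) also passed with the averaged drug, 53 of them in the same direction. Whether the same genes move in either direction more often than precise measurement alone would give was not tested.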
